A study of Triticum urartu and Aegilops tauschii and Triticum urartu x Aegilops tauschii with 45 samples.

How the data were processed

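Endosperm of 2 resynthesized wheat allotetraploids and their 4 diploid parents was sampled 6 days after pollination, and 18 small RNA libraries in 6 groups of 3 were used. Per the labels, RNA was isolated with the miRVana kit and Plant RNA Isolation Aid, and libraries were made with standard Illumina protocols. The submitters' processing notes name CASAVA 1.8.2, TopHat, Cufflinks, Cuffdiff, cutadapt and Bowtie without saying which tool was used for which data. The deposited small RNA files give the read count of each distinct sequence of 18 to 30 nt per library, with no normalization, as the authors made them. How the authors trimmed and selected the reads is not given in the sources used here, nor is a genome build. The values were checked to be whole numbers, and the lengths to lie between 18 and 30 nt. The 27 mRNA samples of the series had no measurement among the files used and were not analysed here. 2 deposited lists of orthologous transcript regions between the A and S genomes were not used, since they hold positions and no measurement. No wheat or Aegilops genome was at hand, so sequences were not mapped and have no position or annotation.

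The library total was the sum of all 18 to 30 nt reads, from 3152427 to 26219798. Levels are in RPM, reads scaled to a library total of 1000000. A sequence with 0 reads in a group was given the limit of 3 reads over the group, for example 0.0884 RPM in SSAA. Folds against 0 reads and ratios with 1 to 3 reads on a side pool the reads and the totals of a group's libraries, so that deep libraries weigh more than in the means. These ratios have exact conditional binomial intervals (Clopper-Pearson, 95%).

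47 miRNA families in 6 lists (development, grass, nutrient, small RNA pathway, anther triggers and tasiRNA) were fixed before the data were examined, with mature sequences from general knowledge. A read of 20 to 22 nt, or 23 nt where the listed sequence is that long, was given to a family when it held bases 2 to 17 of a listed sequence starting within its first 4 bases. The same search with reverse complements gave a median background of 0% of the family's reads among the 26 families tested. Of these miR172 (6 background reads beside 321) and miR9672 (92 beside 2628) had over 1%, as did miR390, miR397, miR398 and miR2275 among the others. Of the 47 families 45 had a read and 26 had a mean of at least 1 RPM and were tested: 11 of 15 for development, 12 of 19 for grass, 2 of 8 for nutrient, 1 of 2 for the small RNA pathway, 0 of 2 anther triggers and 0 of 1 tasiRNA. Structural RNA was the sum of reads within 3 ribosomal, 6 transfer and 2 chloroplast RNA stretches, also from general knowledge, and so undercounts these RNAs. Stowaway reads held the 10-base motif CTCCCTCCGT or its reverse complement.

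The in-silico mid-parent libraries stand for the average of both parents. Replicate i of each parent was thinned at random to the smaller total of the pair and the thinned counts were summed (seed 1). Their totals were 12811417, 6301610 and 10578586 for AADD and 12456558, 15599939 and 31155053 for SSAA. The mixtures average the noise of 2 libraries, and the labels give no pairing behind the replicate numbers used to combine parents, although libraries of SS and TMU06 with the same number deviated together.

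Family counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) scaled by library totals, with all 18 libraries in a group-means fit for comparisons between groups and the 12 tetraploid and mid-parent libraries in another for the mid-parent comparisons. The difference between crosses was the interaction in that fit. Tags were sequences of 20 to 24 nt with at least 5 RPM in at least 3 of the 6 libraries compared, tested with edgeR and TMM factors. All p-values were two-sided and Benjamini-Hochberg adjusted within a comparison, with 0.05 as the threshold. Shares of reads were compared by exact two-sided permutation tests, and differences of shares between crosses by permuting within crosses. Computation outside R used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

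A 24 nt sequence was specific to a parent when it had at least 2 RPM in each of 2 replicates and no read in the same 2 replicates of the other parent. Its parental level was taken in the remaining replicate, so that the choice of sequences did not raise it, and the tetraploid level in the replicate of that number. The 3 rotations gave 3 values per parent, tested with an exact sign-flip permutation test. The expectation of 0.5 assumes that each genome gives the tetraploid an equal part of its reads. Reads were also assigned to parents by their presence in pools of the 2 other replicates.

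Named families were chosen by a rule fixed before the data were examined. It took the families past the threshold, up to 25 by size of fold change against the mid-parent and up to 10 elsewhere, the 5 with the highest mean, miR162 and miR168, and the anther and tasiRNA lists. Named tags were the 3 largest rises and falls past the threshold with a mean of at least 20 RPM and no overlap between the groups. Between 51 and 459 tags met these conditions in each direction of a comparison, where chance leaves 10% of comparisons of 3 against 3 without overlap. D-genome families that were named in the mid-parent comparison of AADD without passing the test were chosen after their values were seen.

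The tests were tried on simulated data. With 100 tags changed by 2 on the log2 scale among tags of a dispersion of 0.1, the test recovered 91% for AADD against mid-parent, 94% for SSAA against mid-parent, 90% for TMU38 against DD and 95% for SS against TMU06. At a change of 1 it recovered 13%, 20%, 12% and 10%. The simulations held 100 tags of each change, and 3, 7, 3 and 8 of the unchanged tags were called falsely. All simulated libraries, those standing for the mid-parent included, were drawn independently with that 1 dispersion and no shift of a whole library. Recovery and false calls in the real libraries can therefore differ from these values. For families, 97.5% of simulated changes of log2 2 were recovered in the mid-parent fit and 96.5% in the fit of 18 libraries. Retention was recovered as 0.802 and 0.399 where 0.8 and 0.4 were simulated.

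Whether replicate numbers pair libraries of different groups was checked by correlating the tags' deviations from their group means. Correlations of the same number were above 0.1 for all 3 numbers in SS and TMU06 (0.147 to 0.246), TMU38 and TMU06 (0.222 to 0.398) and SSAA and TMU06 (0.109 to 0.611), and not in the other pairs. Counts from replicates differed by more than Poisson noise in every group (chi-square per degree of freedom 6.35 to 63.5), so no library was a copy of another.

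Alternatives were TMM or DESeq2 1.42.0 size factors with its Wald test, totals of 20 to 24 nt reads without structural RNA, a replicate block, exact mature sequences, other filters on low counts, a second seed, a log-scale contrast with the mean of the parents' logs, limma 3.58.1 on log2 of RPM plus 1, shares of distinct sequences, other definitions of parent-specific sequences, and leaving out each replicate in turn.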

Results

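Small RNAs of 18 to 30 nt were sequenced from endosperm, the nutritive tissue of the seed, collected 6 days after pollination from 2 resynthesized wheat allotetraploids and their diploid parents. The tetraploid AADD (line AT2) came from Triticum urartu accession TMU38 (AA, the mother) pollinated by Aegilops tauschii accession TQ27 (DD). The tetraploid SSAA (line TLTU) came from Aegilops longissima accession TL05 (SS, the mother) pollinated by T. urartu accession TMU06 (AA). Each of the 6 groups had 3 libraries, 18 in all, and the 27 mRNA samples of the series were not analysed here. Library totals ran from 3152427 reads in DD replicate 2 to 26219798 reads in TMU38 replicate 2. They were 8689009, 26219798 and 17543314 for TMU38, 6406468, 3152427 and 5288361 for DD, and 15120333, 17083187 and 4831106 for AADD. For the other cross they were 14615357, 7799114 and 17880271 for SS, 6228307, 11544858 and 15577597 for TMU06, and 13666770, 12075782 and 8188054 for SSAA. A library held 710387 to 4007226 distinct sequences, of which 75.8% to 81.2% were seen in a single read. The labels do not say whether replicates were separate plants, so the p-values measure a spread between libraries that may be technical. Intervals and detection limits cover counting error only.

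The size classes address whether joining 2 genomes changed the balance between heterochromatic small interfering RNAs, which are mostly 24 nt long and silence transposons, and the 21 nt class that holds most microRNAs (miRNAs). The most frequent length was 24 nt in all 18 libraries. The 24 nt class took 39.3% ± 8.16 (SD, n = 3) of the reads in AADD, against 25.96% ± 2.72 in its in-silico mid-parent, an equal mixture of reads from both parents. In SSAA it took 27.5% ± 1.81, against 23.3% ± 4.05 in the mid-parent. The parents themselves had 26.5% ± 3.72 (TMU38), 25.4% ± 5.08 (DD), 25.6% ± 6.05 (SS) and 20.98% ± 2.50 (TMU06). The AADD libraries held 31.1%, 39.3% and 47.4%, all above the mid-parent libraries, whose highest value was 28.2%. An exact two-sided permutation test gave p = 0.1 for AADD, the smallest p that 3 against 3 allows, and p = 0.2 for SSAA (adjusted p = 0.25 and 0.4 over 10 comparisons of shares).

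The 21 nt class held 5.96% ± 2.24 of the reads in AADD and 6.75% ± 0.414 in its mid-parent (exact permutation p = 0.7, n = 3 each). That difference of −0.784 percentage points ran from −1.98 to 0.243 when a replicate was left out. It lay further below 0 by 20 to 24 nt totals, as given below. In SSAA the 21 nt class held 5.73% ± 0.854 against 7.50% ± 0.473, without overlap between the libraries (exact permutation p = 0.1). Reads of the 47 miRNA families searched made up 0.628% ± 0.0250 of the AADD libraries and 0.513% ± 0.0498 of their mid-parent, again without overlap (p = 0.1, exact permutation). That difference of 0.115 percentage points was 0.00331 by 20 to 24 nt totals and −0.00447 counting distinct sequences. The miRNA share was 0.340% ± 0.106 in SSAA and 0.312% ± 0.0845 in its mid-parent (exact permutation p = 0.9). Fragments of ribosomal RNA, transfer RNA and chloroplast RNA, which rise when RNA breaks down, took 4.12% ± 1.09 in AADD against 4.89% ± 0.228 and 4.27% ± 1.07 in SSAA against 5.49% ± 1.22 (exact permutation p = 0.3 and 0.4). Reads with the terminal motif CTCCCTCCGT of Stowaway elements, short inverted-repeat transposons common in grasses, took 0.0109% ± 0.00209 in AADD against 0.00701% ± 0.00107, without overlap (exact permutation p = 0.1). In SSAA the Stowaway share was 0.00705% ± 0.00138 against 0.00684% ± 0.00184 (exact permutation p = 0.9). Chance leaves 10% of such comparisons without overlap, and no share passed an adjusted p of 0.05. The difference between the crosses was 9.06 percentage points for the 24 nt share (p = 0.3 in a permutation within crosses, 400 regroupings), and its adjusted p was 0.6 or more for all 5 shares.

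**Figure D1:**
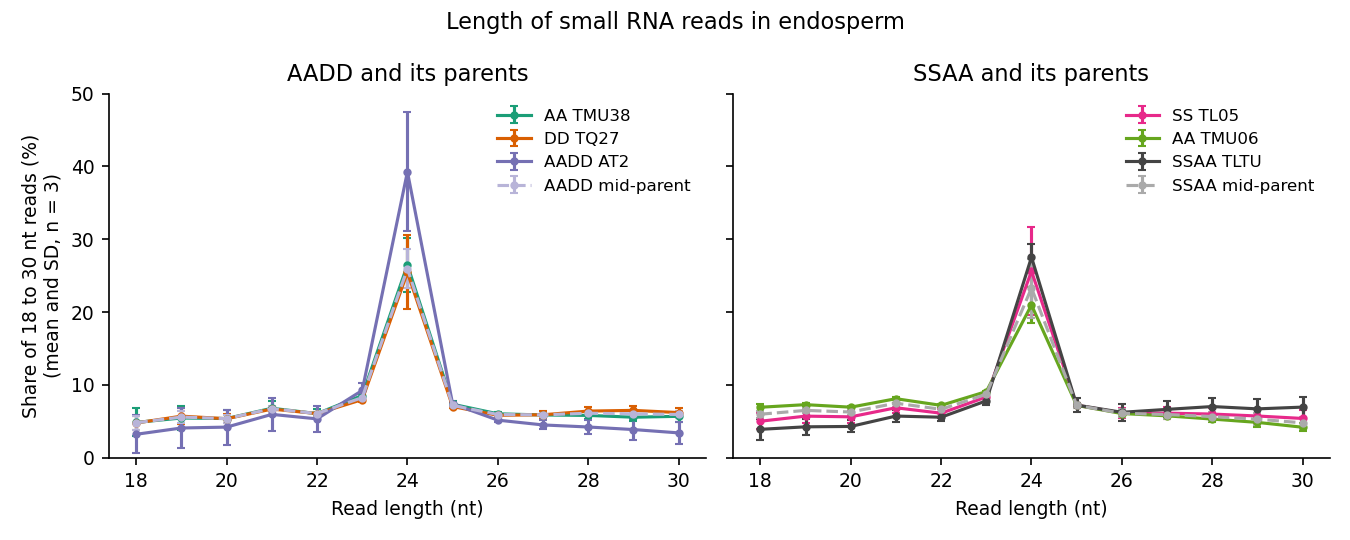
Percent of all 18 to 30 nt reads (vertical axis) at each read length in nt (horizontal axis) for the diploid parents, the tetraploids and the in-silico mid-parents, as means of 3 libraries with SD. The 24 nt class is the highest in every group and reaches 39.3% in AADD against 25.96% in its mid-parent.

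Chloroplast fragments were taken as a sign of green maternal seed tissue, an origin that was not tested. They ran from 0.0483% ± 0.00583 of the reads in DD to 0.0848% ± 0.0185 in SSAA (group means ± SD, n = 3). They took 0.0779% ± 0.00379 in TMU38 and 0.0697% ± 0.0278 in AADD. The anther markers miR2118 and miR2275, triggers of phased small RNAs in anthers, were close to absent. miR2118 had 1 read in AADD and 1 in SSAA, and miR2275 had 3 reads in TMU06 and 0 elsewhere. The trans-acting small RNA tasiARF, which targets auxin response factors, lay between 0.235 ± 0.206 RPM (reads scaled to a library total of 1000000) in TMU06 and 1.197 ± 0.438 in DD (n = 3 each).

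How far the genomes share small RNA sequences was measured by looking up each library's reads in pools of 8440788 reads of 18 to 30 nt drawn from the 2 other replicate numbers of every group. The pools were matched in this total and not in their number of 24 nt reads, so they differed in depth at 24 nt. At 24 nt, 79.6% ± 1.62 of the TMU38 reads were found in the TMU38 pool and 66.5% ± 2.43 in that of the other T. urartu accession, TMU06. In the DD pool 36.9% ± 5.23 were found, and 29.7% ± 3.83 of the DD reads were found in the TMU38 pool. The AADD pool held 77.3% ± 1.68 of the TMU38 reads and 76.6% ± 2.30 of the DD reads. The SSAA pool held 69.9% ± 1.37 of the SS reads and 70.7% ± 1.02 of the TMU06 reads. In their own pools 80.4% ± 0.742 of the DD, 80.0% ± 0.480 of the SS and 74.0% ± 1.73 of the TMU06 reads were found. At 21 nt, 76.8% to 86.8% of a group's reads were found in the pools of the other groups.

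The parents of AADD were compared to show which miRNA families differed between an A-genome and a D-genome accession. Each parent was a single accession, so differences between genomes cannot be told apart from differences between accessions in this comparison. The clearest difference was miR9863, a family known to target immune receptor genes of the Mla type in barley. It reached 2032 ± 128 RPM in DD and 0.514 ± 0.260 in TMU38 (log2 fold change −11.83, SE 0.41, edgeR adjusted p = 3.59e-14). miR9653 had 3457 reads in DD and 1 in TMU38, a ratio of 12213 with a 95% counting interval of 2191 to 482519. miR9677 reached 7.56 ± 1.44 RPM in DD and had no read in TMU38, which puts it at least 138-fold lower there (reads pooled over the libraries, floor of 3 reads over the group). Such folds and the ratios of reads weigh deep libraries more than the means do, and can lie above or below the ratio of the means. miR9672 reached 93.1 ± 31.8 in DD against 0.872 ± 0.156 in TMU38, and miR5071 had 117 reads against 1, a ratio of 413 (interval 72.7 to 16464), with 9.59 ± 8.23 RPM in DD and 0.624 to 16.8 in its libraries.

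Across the 26 families tested, 17 were lower in TMU38 than in DD and 0 were higher (edgeR, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 there were also 17. Of the 12 grass families tested 10 were lower, as were 5 of the 11 developmental families and both nutrient families, with the same counts when adjusted over the list alone. miR156, which restrains SPL transcription factors and keeps plants juvenile, was at 7.06 ± 2.47 in TMU38 and 44.0 ± 12.7 in DD (log2 −2.63, SE 0.38, adjusted p = 1.44e-05). miR396, which targets growth-regulating factors, was at 199 ± 45.7 against 614 ± 131 (log2 −1.63, adjusted p = 7.79e-05). miR172, which targets AP2-like genes, had a log2 fold change of −2.24, miR827 of −2.69, miR1432 of −1.94 and miR169, which targets NF-YA genes, of −1.91. miR5048 was lower in TMU38 at log2 −0.80 (adjusted p = 0.0435). miR166, which targets class III HD-ZIP genes and was the most abundant family, was at 2717 ± 55.1 against 2778 ± 767 (log2 −0.03). miR168, which targets AGO1, had a log2 fold change of −0.64 (adjusted p = 0.406). DESeq2, which centres the fold changes on the families themselves, gave 4 higher and 8 lower, ended the calls of miR172, miR1432, miR169 and miR396, and turned miR166, miR168 and miR5048 to log2 0.91, 0.25 and 0.12. The call of miR5048 was also lost without TMU38 replicate 1 (log2 −0.63) or 2 (−0.68) and without DD replicate 1 (−0.82) or 3 (−0.67).

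The same comparison for the parents of SSAA showed miR9863 on the S-genome side. It reached 56.9 ± 6.98 RPM in SS and 0.218 ± 0.0892 in TMU06 (log2 7.86, SE 0.38, edgeR adjusted p = 9.21e-12). miR9664 went the other way, with 0.111 ± 0.104 in SS and 7.53 ± 2.02 in TMU06 (log2 −6.08, SE 0.54, adjusted p = 5.29e-08). miR5071 was higher in SS, at 7.01 ± 4.08 against 0.165 ± 0.161 (log2 5.69). Of the 26 families 5 were higher in SS and 2 lower, among them 4 developmental families. miR172 was higher by 2.65 on the log2 scale, miR171, which targets GRAS genes, by 1.64, and miR319, which targets TCP genes, by 1.40. miR167, which targets auxin response factors, was at 36.8 ± 4.96 in SS against 106 ± 17.4 in TMU06 (log2 −1.52, adjusted p = 0.000209).

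The counts when adjusted over the list alone were 5 developmental and 3 grass families. miR166 differed by log2 0.08 and miR396 by 0.04, and both turned to −0.15 with DESeq2. miR168 and miR5048 had log2 values of −0.48 and −0.83 without passing the test (adjusted p = 0.762 and 0.0688); miR5048 passed it with the block (−0.83), with DESeq2 (−0.98) and by 20 to 24 nt totals (−0.87). With the replicate number as a block, since libraries of the same number deviated together in these 2 groups, the test called 10 families, 6 higher and 4 lower, as did DESeq2. Without SS replicate 3 or TMU06 replicate 1 or 2 the call of miR319 was lost (log2 0.85, 1.18 and 1.24), and with exact mature sequences alone that of miR167 was lost (log2 −0.83).

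**Figure D2:**
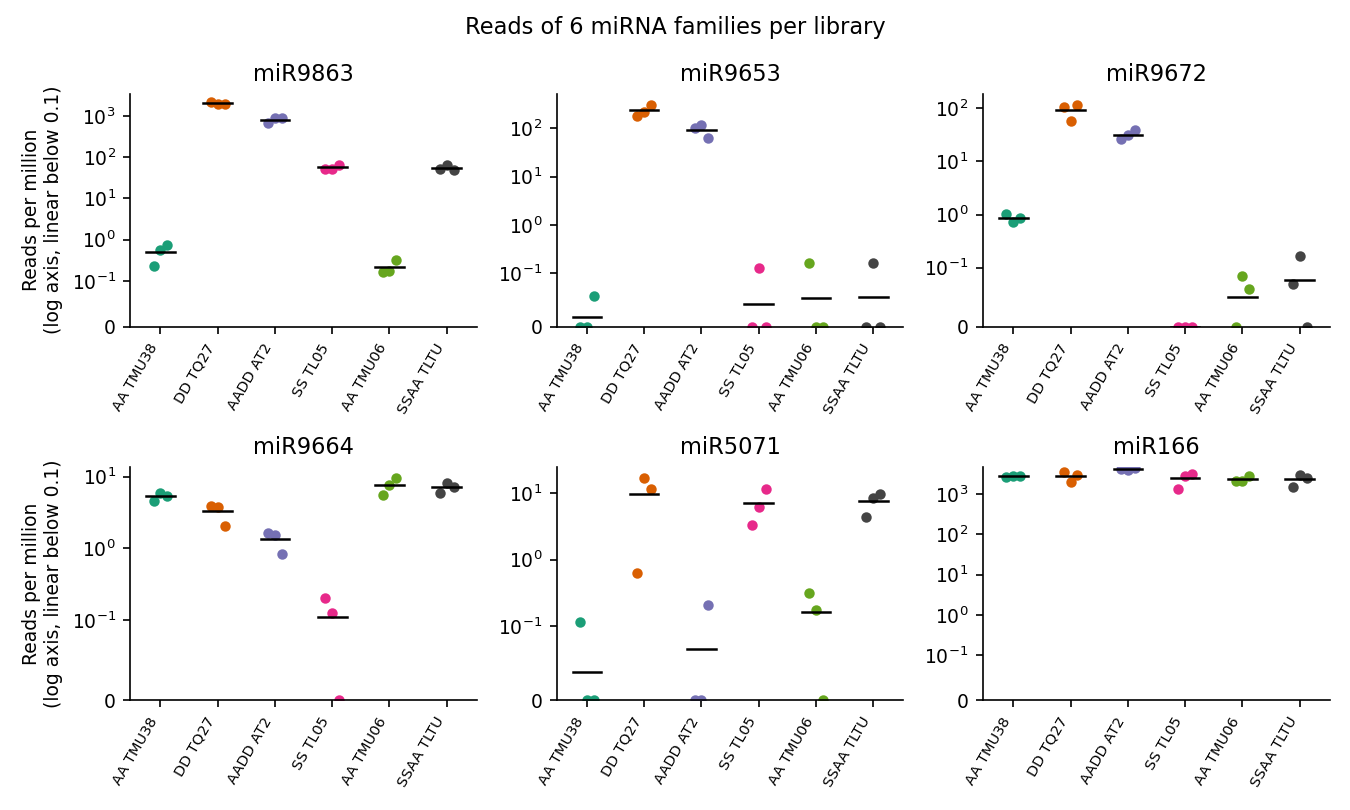
RPM of 6 miRNA families (vertical axes, logarithmic above 0.1 and linear below) in each of the 18 libraries by group (horizontal axis), where a point is a library and a line the mean of 3. miR9863 has a mean of 2032 in DD, 818 in AADD and 56.9 in SS against 0.514 and 0.218 in the T. urartu accessions.

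The A-genome parents TMU38 and TMU06, which belong to the same species, served as a yardstick. They differed in 6 of the 26 families, 5 higher in TMU38 and 1 lower (edgeR), beside 7 families between SS and TMU06. Of these 6, miR9672, miR156 and miR1432 were also called between TMU38 and DD, and miR319 and miR171 between SS and TMU06. Such calls thus also arise between accessions of the same species. miR319 was at 10.7 ± 5.30 in TMU38 against 2.31 ± 1.19 in TMU06 (log2 2.15). miR393, which targets auxin receptors of the TIR1/AFB group, was at 6.17 ± 1.96 against 1.68 ± 0.603 (log2 1.84). miR156 was at 7.06 ± 2.47 against 20.8 ± 3.18 (log2 −1.56). miR9672 had 43 reads against 2, a ratio of 13.7 (interval 3.56 to 116), where the reverse-complement search gave 8 and 12 background reads, so that its level in TMU06 was not above background. miR1432 was higher by log2 2.26 and miR171 by 1.01. miR166, miR396, miR168, miR5048 and miR9863 did not pass the test, with log2 values of 0.26, −0.002, −0.18, −0.16 and 1.19; DESeq2 turned miR166 to −0.08, and scaling by TMM turned miR396 to 0.19 and miR5048 to 0.06. DESeq2 gave 4 higher and 2 lower and ended the call of miR171. Without TMU38 replicate 3 or TMU06 replicate 1 or 2 the call of miR171 was lost (log2 0.92, 0.77 and 0.93).

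Each tetraploid was then compared with its mid-parent, which asks whether its miRNAs departed from the average of its parents. In AADD, miR9664 and miR5071 fell below the average of the parents. miR9863 was at 818 ± 136 RPM in AADD against 1017 ± 63.8 in the mid-parent (log2 −0.31, SE 0.19, edgeR adjusted p = 0.310), and passed the test as lower when scaled by 20 to 24 nt reads (log2 −0.61). miR9653 was at 93.5 ± 28.0 against 117 ± 33.5, miR9672 at 31.9 ± 6.39 against 47.1 ± 15.8, and miR9677 at 2.88 ± 0.178 against 3.78 ± 0.722, none of which passed the test. miR9664 fell to 1.33 ± 0.444 from 4.55 ± 0.182 in the mid-parent (log2 −1.69, SE 0.29, adjusted p = 0.00270), below both parents. miR5071 had 1 read in AADD and 118 in the mid-parent, a ratio of 147 with a counting interval of 25.9 to 5862 (adjusted p = 0.00505); the mid-parent libraries ranged from 0.390 to 8.41 RPM.

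Of the 26 families 0 rose and 2 fell in AADD (edgeR), both of them grass families. The count adjusted over the list alone was 2 for the grass families and 0 for the developmental, nutrient and small RNA pathway lists. At an unadjusted p under 0.05 there were 6 families, and 11 of the 26 had no overlap between tetraploid and mid-parent libraries. Chance gives 10% if all libraries have the same spread. The mixtures average noise and the families share library totals, so the 26 are not separate trials against that 10%. DESeq2 called 1 higher and 3 lower, limma 1 and 4, and a contrast on the log scale 5 and 1. miR166 was at 4088 ± 253 against 2755 ± 375 (log2 0.57, adjusted p = 0.2003) and miR396 at 300 ± 29.2 against 408 ± 55.1 (log2 −0.45, adjusted p = 0.227; −0.74 and called when scaled by 20 to 24 nt reads, which gave 7 calls in all). miR168 and miR5048 had log2 values of 0.65 and 0.25 (adjusted p = 0.677 and 0.710); miR5048 turned to −0.05 when scaled by 20 to 24 nt reads. The miR5071 call was lost without AADD replicate 1 (log2 −6.33) and in the log-scale contrast (−3.78), which also turned miR9863 to 4.60.

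In SSAA the called families lay above the mid-parent. miR9863 rose to 56.1 ± 9.07 RPM from 29.3 ± 3.23 (log2 0.94, SE 0.20, edgeR adjusted p = 0.0132), beside 56.9 ± 6.98 in the SS parent. miR9664, brought in by TMU06, rose to 7.06 ± 1.06 from 3.91 ± 0.944 (log2 0.84, SE 0.26, adjusted p = 0.0473). miR393 rose to 5.17 ± 2.03 from 1.84 ± 0.829 (log2 1.44, SE 0.37, adjusted p = 0.0201) and miR1432 to 1.09 ± 0.549 from 0.225 ± 0.140 (log2 2.03, SE 0.51, adjusted p = 0.0201). miR396 rose to 330.5 ± 84.9 from 203 ± 23.03 (log2 0.70, SE 0.22, adjusted p = 0.0473).

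Of the 26 families 5 rose and 0 fell in SSAA (edgeR), 2 developmental and 3 grass families, or 1 and 3 when adjusted over the list alone. The same 5 had an unadjusted p under 0.05 and were without overlap between the libraries, where chance gives 10% of 26, with the limits given for AADD. miR166 was at 2289 ± 739 against 2336 ± 633 (log2 −0.03, or 0.12 with TMM), and miR168 and miR5048 had log2 values of 0.56 and 0.29 without passing the test. DESeq2 called 2 families, both higher, without miR9863 (log2 0.74), miR9664 (0.66) and miR396 (0.42), and a fit with the replicate number as a block called 3, without miR9664 and miR396; miR396 was also lost with TMM and limma. Of the calls 0 were left without mid-parent replicate 1 or 2, 1 without SSAA replicate 3 and 3 without SSAA replicate 2, while the log2 values of the 5 families stayed above 0 with any library left out, at 0.55 to 0.90 for miR396 and 1.60 to 2.79 for miR1432.

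**Figure D3:**
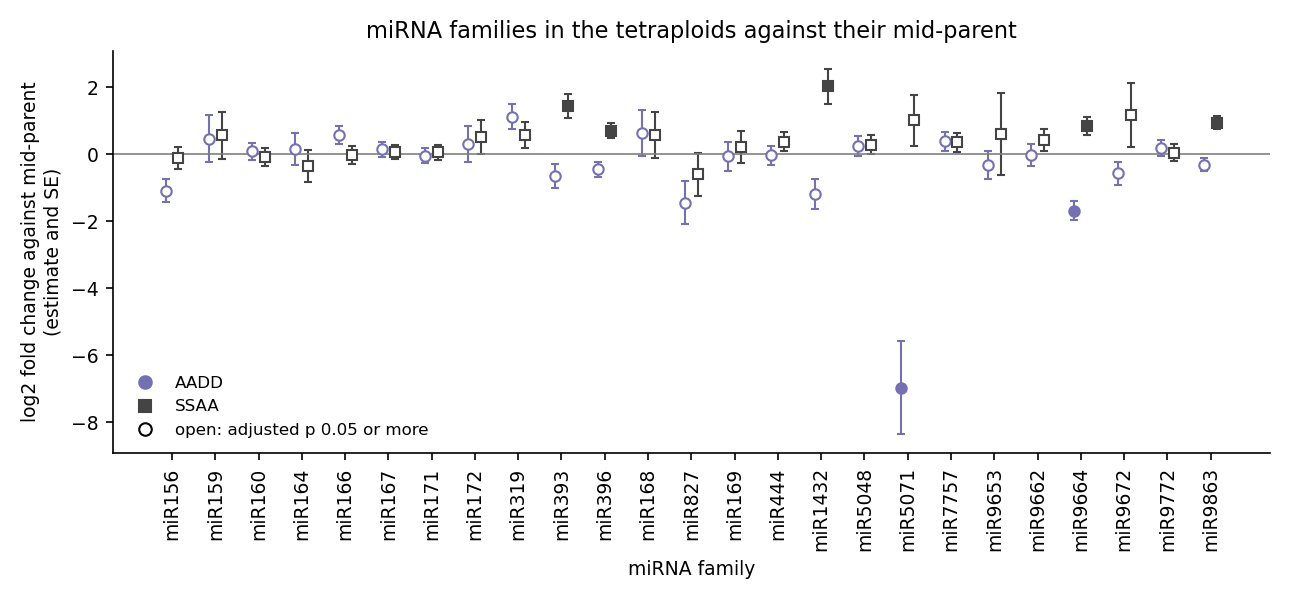
Log2 fold change of each of 25 miRNA families (horizontal axis) against the mid-parent (vertical axis, estimates with SE) in AADD (circles) and SSAA (squares), with called families as filled symbols. miR5071 (−6.96) and miR9664 (−1.69) lie below 0 in AADD, and miR1432 (2.03), miR393 (1.44), miR9863 (0.94), miR9664 (0.84) and miR396 (0.70) above 0 in SSAA.

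Whether the crosses differed was tested as the difference of their changes against the mid-parent. For 6 families the change in AADD lay below that in SSAA, and for 0 above (edgeR; 6 at an unadjusted p under 0.05; DESeq2 gave 6 below and 1 above, limma 6 and 0). They were miR9664 (difference of log2 fold changes −2.52, SE 0.39, adjusted p = 0.00106), miR1432 (−3.21, SE 0.67, adjusted p = 0.00470), miR5071 (−7.97, SE 1.63, adjusted p = 0.00470), miR9863 (−1.25, SE 0.27, adjusted p = 0.00488), miR393 (−2.10, SE 0.51, adjusted p = 0.00821) and miR396 (−1.15, SE 0.32, adjusted p = 0.0162). Adjusted over the list alone, 2 developmental and 4 grass families passed. miR166, miR168 and miR5048 had differences of 0.60, 0.09 and −0.04 without passing the test; miR168 turned to −0.07 with TMM and miR5048 to 0.12 with DESeq2, which called miR166 (0.78). The calls of miR9863 and miR396 were lost with TMM, where the differences were −1.24 and −1.18, and in the log-scale contrast miR9863 turned to 0.69 and the calls of miR5071 (−6.72) and miR396 (−0.93) were lost. miR396 was also lost without AADD mid-parent replicate 1 (−1.06) or SSAA mid-parent replicate 2 (−1.08).

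Against its single parents, AADD had more of miR9863, miR9653, miR9672 and miR9677 than TMU38 and less of them than DD. Relative to TMU38, 9 families were higher and 1 lower (edgeR). miR9863 was higher by log2 10.51 (SE 0.39), miR9672 by 5.21 and miR9653 by a ratio of 5416 (3824 reads against 1, interval 971 to 213973). miR9677 was at least 51.5-fold higher. miR172, miR319, miR169, miR7757 and miR9772 were higher by log2 1.69, 1.44, 1.26, 1.07 and 0.81, calls that DESeq2 ended (4 higher and 1 lower in all), and miR9664 was at log2 −1.91. Without TMU38 replicate 1 the calls of miR172, miR169, miR7757 and miR9772 were lost (6 calls), without replicate 3 those of miR319, miR169 and miR9772, without replicate 2 that of miR319, and without AADD replicate 1 those of miR172, miR169 and miR9772 (7 calls). Among the abundant families miR166, miR396, miR168 and miR5048 had log2 values of 0.59, 0.59, 0.98 and 0.71 without passing the test, and DESeq2 turned miR166 to −0.10 and miR396 to −0.11, whereas TMM called miR166 (1.05), miR396 (1.07) and miR5048 (1.18). Totals of 20 to 24 nt reads ended the calls of miR172, miR169 and miR9772, and exact mature sequences that of miR169.

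Relative to DD, 11 families were lower in AADD and 0 higher (edgeR; DESeq2 gave 2 higher and 8 lower). At an unadjusted p under 0.05 there were also 11. miR9863, miR9653, miR9677 and miR9672 had log2 values of −1.31, −1.32, −1.39 and −1.55, where the additive expectation for sequences of a single parent is −1. The log2 values were −1.89 for miR156, −1.86 for miR1432, −1.32 for miR393, −1.201 for miR9664 and −2.23 for miR827, and miR5071 had a ratio of 292 (interval 51.4 to 11624). miR396 had a log2 value of −1.04, miR166 of 0.56, miR168 of 0.35 and miR5048 of −0.10, of which miR396 alone passed the test and miR5048 turned to 0.12 with TMM. DESeq2 ended the calls of miR396, miR9677 and miR9664 and called miR166 (0.81), TMM ended those of miR393, miR9653 and miR396 (−0.87), and exact mature sequences those of miR9653 and miR9664. The calls of miR827 (−1.19) and miR9653 (−1.08) were lost without DD replicate 3, that of miR9653 also without AADD replicate 1 or 3, and that of miR9664 without AADD replicate 2 or 3 or DD replicate 1 or 2.

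SSAA had 4 families higher than SS and 0 lower (edgeR; DESeq2 gave 3 and 1; 7 at an unadjusted p under 0.05). miR9664 was higher by log2 5.98 (SE 0.54), miR1432 by 1.85, miR393 by 1.499 and miR167 by 1.001. miR9863 differed from SS by log2 −0.02, which turned to 0.29 with TMM. miR166, miR396, miR168 and miR5048 had values of −0.07, 0.69, 0.83 and 0.78 without passing the test, and miR166 turned to 0.23 with TMM. Without SSAA replicate 2 or 3, or SS replicate 1 or 2, the calls of miR1432, miR393 and miR167 were lost and 1 family was called. With exact mature sequences the same calls were lost, with miR1432 at log2 2.19, miR393 at 1.39 and miR167 at 0.14, and DESeq2 ended that of miR1432; the block called miR5048.

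Relative to TMU06, 7 families were higher in SSAA and 0 lower (edgeR; DESeq2 gave 6 and 1 and ended the call of miR171; 9 at an unadjusted p under 0.05). miR9863 was higher by log2 7.84 (SE 0.38), miR5071 by 5.78, miR172 by 2.37, miR1432 by 2.13, miR393 by 1.56, miR319 by 1.45 and miR171 by 1.096. miR396 had a log2 value of 0.73 (adjusted p = 0.0519; called with TMM at 1.15 and by 20 to 24 nt totals at 0.71), miR166 of 0.01, miR168 of 0.35 and miR5048 of −0.05, of which miR166 turned to −0.46 and miR168 to −0.01 with DESeq2 and miR5048 to 0.34 with TMM. Without TMU06 replicate 2 there were 3 calls, with miR171, miR319, miR1432 and miR393 lost, and without SSAA replicate 3 there were 4, with miR319, miR1432 and miR393 lost; miR319 was also lost without SSAA replicate 2 or TMU06 replicate 1. miR162, which targets DCL1, had 1 read in TMU06, 2 in SSAA and 0 in the other groups, too few for a test in any comparison.

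Single sequences, called tags, were compared between the parents to show how far these accessions carry their own small RNAs. They are given by sequence alone, since no genome assembly was at hand on which to place them. Between TMU38 and DD, 3773 of 13201 tags were higher in TMU38 and 3445 lower (edgeR). At 24 nt the counts were 3001 and 2779 of 7161. No DD read was seen for 2230 tags and no TMU38 read for 1974. Among the 8997 tags read in both, 1543 were higher and 1471 lower. The 24 nt tag ATGTAGAAAAGCTAACCTAGAGAA reached 149 ± 42.0 RPM in TMU38 and no read in DD, at least 742-fold higher in pooled reads. ATTGGAATACATGTAGAAAAGCTA at 137 ± 47.7 was at least 677-fold higher and CAACCTGTAGAAGTGTGCCGAGAA at 126 ± 26.1 at least 604-fold. On the DD side the 21 nt tag CCACCGTCTGGTTCAACGAGC at 230.4 ± 97.5 was at least 3951-fold lower in TMU38. AGTGATTGCAAGCTGAATAGAGTT at 204 ± 59.7 was at least 3795-fold lower and CGAGAACATTGACCTTGAGCCAAG at 154 ± 32.3 at least 2822-fold.

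Between SS and TMU06, 2888 of 11589 tags were higher in SS and 1523 lower (edgeR). No TMU06 read was seen for 1876 tags and no SS read for 425. Among the 9288 read in both, 1012 were higher in SS and 1098 lower. CTTCGGTCATATCGTCGCGGAGCT reached 301 ± 142 RPM in SS, at least 3532-fold higher than in TMU06 (pooled reads, as for all folds against 0 reads). ATTGGTTGGGTTGTAGGATCCGGC at 275.5 ± 111 was at least 3198-fold higher and AACTGACCAACAACTCTTTACTGT at 230.2 ± 127 at least 2670-fold. On the TMU06 side TAAAGATTGATATACTGAAAGCCT at 43.5 ± 24.01 was at least 513-fold lower in SS. TCCTTGGCTGCCATTTCACTCTGA had 1 read in SS and 3756 in TMU06, a ratio of 4538 (interval 814 to 179290). ACGGACACCCTATGCGAACACATA had 1 and 3105 reads, a ratio of 3751 (673 to 148223).

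Against the mid-parent, more 24 nt tags rose in AADD than fell. Of 13150 tags 1130 rose and 307 fell (edgeR), an order that turned round without AADD replicate 3 (25 rises and 58 falls), and of the 7401 tags of 24 nt 1015 rose and 96 fell. Of the 1400 tags of 21 nt 3 rose and 52 fell. The median log2 fold change was 0.67 at 24 nt and −0.33 at 21 nt. These shifts go with the 24 nt share of reads, which was 1.51 times that of the mid-parent (exact permutation p = 0.1). The counts by length are therefore not separate evidence from that share. Among 24 nt tags read in TMU38 alone 437 of 2038 rose (21.4%) and 11 fell. Among those read in DD alone 331 of 1948 rose (16.99%) and 29 fell, and among those read in both parents 247 of 3415 rose (7.23%) and 56 fell. Tags of a single parent are diluted in the mid-parent and could pass the filter through AADD. These percentages by class can partly reflect the filter. Of the 402 tags from ribosomal, transfer or chloroplast RNA 0 rose and 5 fell (edgeR, 18 at an unadjusted p under 0.05). Of the 28 tags of miRNA families 0 rose and 0 fell (edgeR, 2 at an unadjusted p under 0.05).

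The 3 largest rises were tags that DD alone carried. TGCCTGAGACAAATGTAGCAACTC was at 39.4 ± 8.07 RPM in AADD against 3.06 ± 1.75 in the mid-parent (log2 3.59, SE 0.52, adjusted p = 7.54e-05). TGACGAGGACAGTGACAAAGGTTT was at 39.3 ± 9.15 against 3.43 ± 1.36 (log2 3.42) and GTATGCAACGGACCATGAGGACGT at 48.4 ± 7.77 against 4.88 ± 2.30 (log2 3.22). Of the tags that fell, 23 had no read in AADD. CGTAGACCTCATGGAGCGGAACCT, read in both parents, was at 86.0 ± 26.4 in the mid-parent and at least 1133-fold lower in AADD in pooled reads. CGCCTTTGACGGGTTGCTCGGCAC, read in DD alone, was at 41.5 ± 19.2 and at least 564-fold lower, and AGAATATGGACTAAGGGAATCCCT, read in both, was at 41.0 ± 11.9 and at least 538-fold lower. DESeq2 gave 1214 rises and 479 falls, and without ribosomal, transfer and chloroplast tags there were 797 rises and 424 falls. The number of calls moved with single libraries of either side: 83 were left without AADD replicate 3, 562 rises and 265 falls without replicate 2, and 2459 and 1143 were called without replicate 1; without a mid-parent replicate there were 473, 373 and 583 calls in all.

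In SSAA 1362 of 11246 tags rose and 361 fell (edgeR), and at 24 nt 1151 and 221 of 5321. Of the 1464 tags of 21 nt 46 rose and 38 fell. The median log2 fold change was 0.55 at 24 nt and −0.39 at 21 nt. The 24 nt share of reads was 1.18 times that of the mid-parent (exact permutation p = 0.2). As in AADD, the counts by length are not separate evidence from that share. Among 24 nt tags read in TMU06 alone 276 of 503 rose (54.9%) and 11 fell (2.19%). Among those read in SS alone 237 of 1619 rose (14.6%) and 136 fell (8.40%). Among those read in both 507 of 3068 rose (16.5%) and 74 fell. A further 131 tags of 24 nt had no read in either parent. All 131 are among the rises, since they could only lie above the mid-parent. A tag of a single parent is diluted in the mid-parent, so it could enter the test through its level in SSAA. Tested here were 503 tags of TMU06 alone and 1619 of SS alone, beside 391 and 1745 between the parents. The percentages by class can partly reflect this filter.

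The largest rises in SSAA were GAAGTAACAAACACTGGACGCCT (23 nt, 70.8 ± 20.4 RPM, at least 1356-fold in pooled reads) and CGCACACTTGTCAACGAGGACATG (56.2 ± 4.46, at least 1097-fold), neither of which was read in a parent. AATAGATCTTTGATATTCAAGCCT (50.8 ± 7.25, at least 1004-fold) was read in SS but not in the thinned mid-parent. The largest falls were tags of SS. ACTCAGGCACTCGGATGTAGATCC, at 52.0 ± 17.1 in the mid-parent, was at least 648-fold lower in SSAA in pooled reads, and GTTCTTATTCCGTCAGTAGACAGT, at 40.3 ± 25.9, at least 542-fold. AACCACAACGGCGTAGACCCCATG had 1 read in SSAA and 3248 in the mid-parent, a ratio of 1861 (interval 334 to 73537). DESeq2 gave 1772 rises and 598 falls; 562 rises and 261 falls were left without mid-parent replicate 2, and 844 and 250 without SSAA replicate 1. TMM scaling moved the median fold change of all tags, so that values by library totals lay higher by log2 0.10 in AADD against mid-parent and by 0.17 in TMU38 against DD, and at −0.23 and −0.39 in SSAA against mid-parent and in SS against TMU06. Fold changes of tags are relative to the TMM scale.

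**Figure D4:**
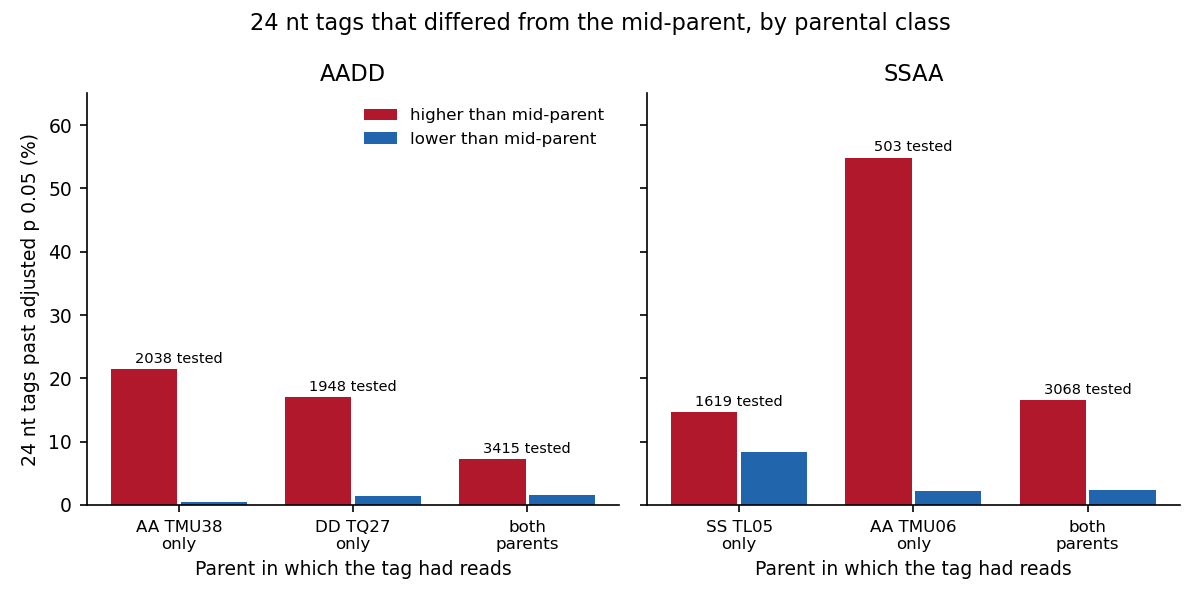
Percent of the tested 24 nt tags called higher or lower than the mid-parent (vertical axis, bars from 0) by the parent in which they were read (horizontal axis) in AADD and SSAA. Tags of TMU06 alone were higher in 54.9% and lower in 2.19% of cases, and tags of SS alone in 14.6% and 8.40%. The 131 tags without a parental read are not drawn. Tags of a single parent could enter the test through a high level in the tetraploid, so the percentages can partly reflect the filter.

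Parent-specific sequences were followed into the tetraploids to ask whether these kept the small RNAs of either parent more than those of the other. A parent's specific 24 nt sequences kept 1.02 ± 0.1297 of their parental level in AADD for TMU38 and 0.851 ± 0.355 for DD, where 0.5 is the additive expectation (n = 3, means of 7175 and 7019 sequences). The log2 ratio of these retentions was 0.35 ± 0.52 (exact sign-flip permutation p = 0.5). In SSAA the maternal SS sequences kept 0.541 ± 0.184 and the paternal TMU06 sequences 0.836 ± 0.165 (7219 and 2690 sequences), a log2 ratio of −0.66 ± 0.39. Its exact sign-flip permutation p was 0.25, the smallest that 3 replicates allow. Relative to all 24 nt reads, an alternative chosen after seeing the data, the retentions were 0.672 ± 0.0254 and 0.528 ± 0.0710 in AADD and 0.488 ± 0.0686 and 0.649 ± 0.0657 in SSAA. Another such alternative kept only sequences with a read in the tetraploid. Its mean retentions were 1.02 and 0.867 in AADD, and 0.607 and 0.848 in SSAA (log2 ratio −0.52). Other alleles in the SS plants sequenced, a candidate raised below, could lower the SS value. The SSAA order therefore does not show that the tetraploid kept less of the maternal genome's small RNAs.

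At 21 nt the SSAA order was the reverse. SS sequences kept 0.695 ± 0.152 and TMU06 sequences 0.339 ± 0.0883, a log2 ratio of 1.05 ± 0.59 over means of 100.3 and 64.7 sequences. At 22 nt they kept 0.657 ± 0.1203 and 0.377 ± 0.0660 (log2 0.80 ± 0.52). In AADD the 21 nt values were 0.491 ± 0.0750 for TMU38 and 0.368 ± 0.0605 for DD (log2 0.42 ± 0.27). The exact sign-flip permutation p was 0.25 for each of these ratios. Without AADD replicate 1 the 24 nt log2 ratio of AADD was 0.06.

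**Figure D5:**
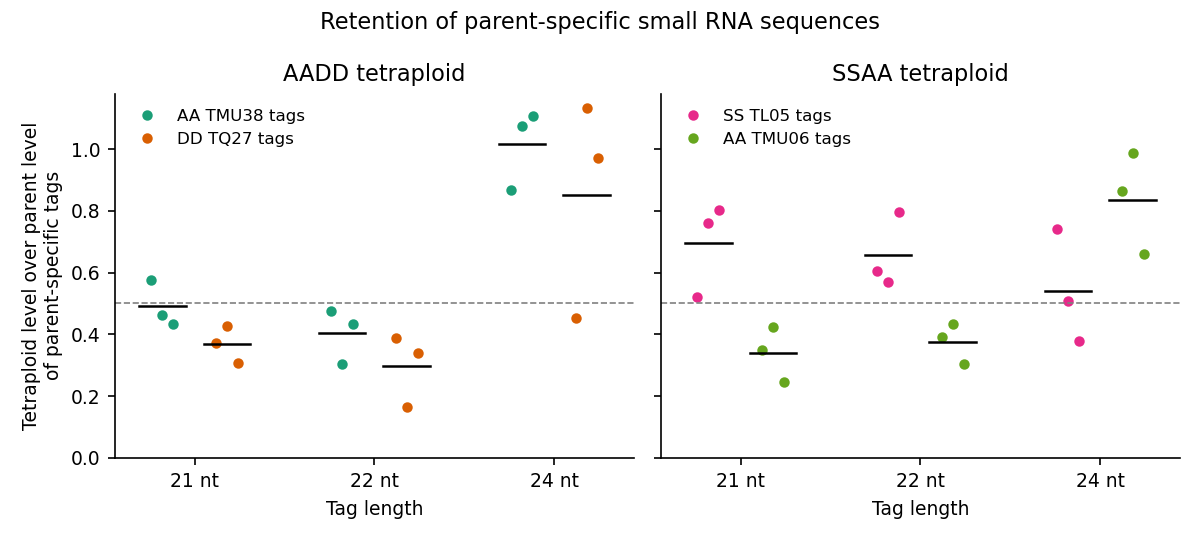
Level of each parent's specific sequences in the tetraploid divided by that in the parent (vertical axis) for 21, 22 and 24 nt (horizontal axis), with a point per replicate, a line at the mean of 3, and the additive expectation of 0.5 as a dashed line. At 24 nt the TMU06 mean in SSAA is 0.836 against 0.541 for SS, and at 21 nt it is 0.339 against 0.695.

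The same question was asked of all 24 nt reads of the tetraploids. In SSAA 19.7% ± 1.56 of the 24 nt reads had sequences found in TMU06 alone, against 14.6% ± 1.32 in the mid-parent (exact permutation p = 0.1, n = 3 each). Sequences found in neither parent pool took 21.3% ± 1.89 in SSAA against 18.4% ± 0.732 (exact permutation p = 0.1). Those found in SS alone took 26.9% ± 1.93 in SSAA against 29.1% ± 6.32 (exact permutation p = 0.6). In AADD sequences found in neither took 18.7% ± 1.72 against 19.4% ± 1.06 (exact permutation p = 0.6). Those of TMU38 alone took 27.8% against 22.5% (exact permutation p = 0.2), and those of DD alone 26.5% against 25.2% (exact permutation p = 0.8). Sequences found in both parents took 26.9% ± 6.30 in AADD against 32.9% ± 3.08 (exact permutation p = 0.2). In SSAA they took 32.1% ± 5.19 against 37.9% ± 7.26 (exact permutation p = 0.4). The classes add up to all 24 nt reads, so their shares are not independent of each other.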

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

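The 6 differences between crosses came from a test chosen before the data were examined, and the test by regrouping was chosen after the result was seen. For miR9664 (difference of log2 fold changes −2.52), miR1432 (−3.21), miR5071 (−7.97), miR9863 (−1.25), miR393 (−2.10) and miR396 (−1.15), the change against the mid-parent in AADD lay below that in SSAA. In AADD the log2 changes were −1.69, −1.18, −6.96, −0.31, −0.66 and −0.45, and in SSAA 0.84, 2.03, 1.01, 0.94, 1.44 and 0.70, in the same order of families. Among 100 regroupings of tetraploid and mid-parent libraries within the crosses, the real one included, 1 gave as many calls. The real one gave 6 and the highest of the others 4. This sets the count against no change in either cross, not against an equal change in both. Chance is therefore not excluded for the difference between crosses. No technical or biological explanation for these 6 differences was tested.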

How the results depend on the processing

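Only the alternatives without structural RNA tags, relative to reads of the same length, and for sequences with a read in the tetraploid were chosen after seeing the data. For single families 1272 alternative values kept direction and side of the threshold, 116 lost and 19 gained a call, and 75 changed sign. All 286 alternative values of the named tags kept both. These tags were picked as the largest changes without overlap, so this says little about other tags. Counts of families stayed within 1.5 times in 112 alternatives and moved further in 33, counts of tags in 31 and 17, and the causes were not tested except where fewer features or libraries entered a test. Leaving out structural RNA gives no value for the structural share itself. The replicate block moved no count by over 1.5 times in SS, TMU38 or SSAA against TMU06. It moved counts of SSAA against mid-parent further, as given below. There the tags' deviations correlated by 0.467, −0.044 and 0.624 for the 3 replicate numbers. Depth limits the families under 1 RPM, which were not tested, and DD replicate 2 with 3152427 reads was the shallowest library.

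Counts of called families moved as follows. In AADD against mid-parent (2) they were 4 with DESeq2, 7 by totals of 20 to 24 nt reads, 6 in the log-scale contrast and 5 with limma. In SSAA against mid-parent (5) they were 2 with DESeq2, 3 with the block and 3 with no filter, and in the difference between crosses (6) 3 in the log-scale contrast. With no filter TMU38 against TMU06 (6) gave 11, with DESeq2 AADD against TMU38 (10) gave 5, and with exact mature sequences SSAA against SS (4) gave 1. With a mean of at least 10 RPM, which tests fewer families, the counts were 0 in AADD against mid-parent (edgeR), 1 in SSAA against mid-parent, 2 in the difference between crosses, 8 in TMU38 against DD, 3 in SS against TMU06 and 3 in TMU38 against TMU06. They were 6 in AADD against TMU38, 5 in AADD against DD, 1 in SSAA against SS and 2 in SSAA against TMU06. Leaving out a replicate gave 1 to 3 in AADD against mid-parent, 0 to 5 in SSAA against mid-parent, 6 to 10 in AADD against TMU38, 1 to 5 in SSAA against SS and 3 to 9 in SSAA against TMU06.

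Signs of abundant families that mostly lay near 0 changed, and the causes were not tested. By totals of 20 to 24 nt reads, miR5048 in AADD against mid-parent was at log2 −0.049, miR168 in the difference between crosses at −0.25, miR9863 in SSAA against SS at 0.016 and miR166 in SSAA against TMU06 at −0.0030. In the log-scale contrast miR9863 was at 4.60 in AADD against mid-parent and 0.69 in the difference between crosses; its construction, a mean of logs with TMU38 near 0 reads, gives this. With TMM, miR166 was at 0.12 in SSAA against mid-parent, miR168 at −0.075 in the difference between crosses, miR396 and miR5048 at 0.19 and 0.064 in TMU38 against TMU06, miR5048 at 0.12 in AADD against DD, miR166 and miR9863 at 0.23 and 0.29 in SSAA against SS, and miR5048 at 0.34 in SSAA against TMU06. With DESeq2, miR5048 was at 0.12 in the difference between crosses, miR166, miR168 and miR5048 at 0.91, 0.25 and 0.12 in TMU38 against DD, miR166 and miR396 both at −0.15 in SS against TMU06, and miR166 at −0.079 in TMU38 against TMU06. DESeq2 also put miR166 and miR396 at −0.10 and −0.11 in AADD against TMU38, miR5048 at 0.19 in AADD against DD, and miR166 and miR168 at −0.46 and −0.015 in SSAA against TMU06. With exact mature sequences, miR166 was at 0.040 in TMU38 against DD, miR396 at 0.0081 in TMU38 against TMU06 and miR5048 at 0.36 in SSAA against TMU06. With the block, miR396 and miR168 were at 0.0027 and 0.053 in TMU38 against TMU06 and miR5048 at 0.0021 in SSAA against TMU06.

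Leaving out a replicate gave these ranges of log2 values: in SSAA against mid-parent −0.24 to 0.21 for miR166 and −0.73 to 1.51 for miR168; in the difference between crosses −0.86 to 1.38 for miR168 and −0.29 to 0.19 for miR5048; and in TMU38 against DD −0.23 to 0.15 for miR166. In SS against TMU06 they were −0.15 to 0.37 for miR166, −0.13 to 0.27 for miR396 and −1.68 to 0.32 for miR168. In TMU38 against TMU06 they were −0.17 to 0.23 for miR396, −0.53 to 0.62 for miR168 and −0.51 to 0.14 for miR5048, and in AADD against DD −0.30 to 0.13 for miR5048. In SSAA against SS they were −0.36 to 0.17 for miR166, −0.16 to 0.085 for miR9863 and −0.47 to 2.03 for miR168, and in SSAA against TMU06 −0.20 to 0.25 for miR166, −0.95 to 1.15 for miR168 and −0.19 to 0.25 for miR5048.

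Counts of called tags in AADD against mid-parent (1437) were 734 with the block, 116 at 20 RPM, and 83 to 3602 when a replicate was left out. In SSAA against mid-parent (1723) they were 2813 with the block, 4530 at 2 RPM, 255 at 20, and 823 to 1908 when a replicate was left out. In TMU38 against DD (7218) they were 18177 at 2 and 1370 at 20 RPM, and in SS against TMU06 (4411) 12699 and 684. More and fewer tags were tested at 2 and 20 RPM. The log2 ratio of retentions in SSAA turned from −0.66 to 1.05 at 21 nt and 0.80 at 22 nt, which are other sequences.

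The differences of shares, in percentage points, moved as follows. By 20 to 24 nt totals the 24 nt share of SSAA differed by 9.86, the 21 nt share of AADD by −3.54 and of SSAA by −3.13, the miRNA share of AADD by 0.00331 and the Stowaway share of SSAA by −0.000523. Counting distinct sequences, the 24 nt share of AADD differed by 5.36, the 21 nt share of SSAA by −0.904, the miRNA share of AADD by −0.00447, the structural share of SSAA by 0.0458 and the Stowaway share of SSAA by −0.000436. Leaving out a replicate gave −1.98 to 0.243 for the 21 nt share of AADD, −0.0129 to 0.0892 for the miRNA share of SSAA and −0.000794 to 0.00101 for the Stowaway share of SSAA. The causes were not tested.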

Other observations

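The tests on AADD's 24 nt share, the depth tests on sequences of SSAA and the splits of the libraries were chosen after the result was seen, unlike those on other libraries of the series and on other alleles. Some families were read in few groups or in none. miR530 had 12 reads in DD (0.831 ± 0.791 RPM, n = 3), 0 in TMU38 and AADD and 2 in SSAA. miR529 and miR535, relatives of miR156, had 0 reads in every group. miR9677 was read in DD and AADD and had 0 reads in TMU38, SS, TMU06 and SSAA, with limits of 0.0572, 0.0745, 0.0900 and 0.0884 RPM. Adenine was the first base of 39.2% to 46.2% of the 24 nt reads in the libraries, the base preferred by the Argonaute proteins that carry heterochromatic small interfering RNAs.

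SSAA held 24 nt sequences that neither parent showed. Of 3922 sequences with at least 5 RPM in all 3 SSAA libraries, 131 (3.34%) had no read in SS or TMU06, against 0 of 5754 in AADD; they formed 107 groups by overlap, had a median of 9.13 and a sum of 1557 RPM, and included ATTTAAGGATCAGTTTGAAGAGAC (46.8 ± 13.6) and AGTAGATTGTCGGCTAAATGCAGA (35.9 ± 5.38). With both parents thinned to 0.5 of their reads the number was 155, 1.18 times as large. Low parental depth thus stays open for some of them. Each still lay at least 60.2-fold above the limit that 0 reads set in a parent, as the choice of abundant sequences implies. Carry-over from the small RNA libraries of TMU38, DD or AADD could account for few of them. At most 0.763% were more abundant there, and 12, 1 and 3 of the 131 had any read in these groups. The mRNA samples of the series were not examined. A candidate explanation is that the SS plants sequenced carry other alleles than the SS plant that made the tetraploid. Of the 131, 19 (14.5%) had a neighbour with 1 mismatch in SS that SSAA lacked. The control was 2 of 426 sequences (0.469%) shared with TMU06 alone (Fisher's exact test, two-sided, p = 5.33e-11). In TMU06 0 of the 131 had such a neighbour, but so did 0 of 1115 sequences shared with SS alone, so TMU06 gives no contrast. Overlapping sequences are not independent, so this p overstates the evidence, and a change made by the cross itself, which the design cannot part from another SS parent, stays open.

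The reverse case was SS sequences missing from SSAA. Of 1745 abundant SS-specific 24 nt sequences 186 (10.7%) had no read in SSAA, against 3 of 391 (0.767%) for TMU06, and 12 of 2019 (0.594%) and 24 of 1774 (1.35%) for TMU38 and DD in AADD. With SSAA thinned to 0.5 of its reads the number was 235, 1.26 times as large, so low depth of SSAA stays open for some of them. Other alleles in the SS parent could give this too. Of the 186, 27 (14.5%) had a neighbour with 1 mismatch that was new in SSAA, against 50 of the 1559 kept (3.21%, Fisher's exact test, p = 3.67e-09). The 186 formed 153 groups by overlap, so this p overstates the evidence. For TMU38 and DD in AADD such neighbours were 0 of 12 and 0 of 24. These are the same kind of pairs as above, counted from the SS side, so this test is not separate evidence. Loss of loci or silencing in the tetraploid was not tested and stays open for the sequences without such a neighbour.

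The 24 nt share was higher in AADD than in its mid-parent by 13.3 percentage points of reads. Counting distinct sequences the gap was smaller, at 42.9% against 37.5%, and the libraries overlapped. By this count the AADD libraries held 35.2%, 46.9% and 46.6%, and the mid-parent libraries 37.2%, 36.1% and 39.3%. AADD replicate 1 thus lay below every mid-parent library. Without AADD replicate 3 the difference in reads was 9.24 points, so this library did not account for all of it. The AADD libraries left are too few to tell whether the rest exceeds the spread between libraries. Fewer ribosomal, transfer and chloroplast fragments stay open: the difference was 13.6 points with the listed ones left out, but these held 4.89% of the mid-parent reads, where a loss of 33.9% of the reads would be needed. Fewer fragments outside 20 to 24 nt cannot be told apart from a real gain: within 20 to 24 nt the share was 61.2% ± 11.8 against 49.4% ± 3.74, a difference of 11.8 points, but AADD replicate 1 with 48.7% lay among the mid-parent libraries at 45.6% to 53.0%. A biological difference between the tetraploid and its parents stays open and was not tested apart from these.

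With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest among the other splits, with 1 split of 10 as large as the real one each time, were 2 and 1 for families in AADD against mid-parent, 5 and 2 in SSAA against mid-parent, 17 and 0 in TMU38 against DD, 7 and 1 in SS against TMU06, and 6 and 0 in TMU38 against TMU06. They were 10 and 0 in AADD against TMU38, 11 and 1 in AADD against DD, 4 and 3 in SSAA against SS, and 7 and 0 in SSAA against TMU06. For tags they were 1437 and 0 in AADD against mid-parent, 1723 and 0 in SSAA against mid-parent, 7218 and 0 in TMU38 against DD, and 4411 and 0 in SS against TMU06.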
